A study of Mus musculus with 2 samples.

How the data were processed

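H3K27ac ChIP-seq peaks of mouse hindbrain at embryonic day 16.5 were analysed in 1 group of 2 biological replicates. Per the labels, each replicate is a pool of male and female embryos of the B6NCrl strain, and fragments of 300 to 500 bp were used. The 4 deposited peak lists in narrowPeak form hold the peaks of each replicate, of the pooled data, and those called replicated. Per the file headers and labels, the positions are on build mm10. The authors' deposited lists give for each peak a fold enrichment (a linear ratio) in column 7, the −log10 of a p-value and of a q-value in columns 8 and 9, and the position of the summit within the peak in column 10. The columns' units were taken from the narrowPeak form and checked against their values. The aligner, the peak caller, its threshold and the rule that made a peak replicated are not given in the sources used here. The labels name a possible control experiment, which was not used here. Per the notes that came with the files, the list of replicate 1 was made from 2 files besides its own reads and that of replicate 2 from 1, without their roles, so the replicates may differ in their control, and the heights and numbers of their peaks with it. Peaks are thus given per replicate and for the pooled data, and all 49032 replicated peaks (74.4% of the pooled list) were identical in position to a pooled peak. Of those on the chromosomes, 72.7% overlapped both replicate lists, 18.0% the replicate 1 list only, 7.11% the replicate 2 list only and 2.16% neither. The lowest −log10 p-value in a deposited list was between 2.00 and 2.05, and 90.4% of replicate 1 peaks, 81.7% of replicate 2 peaks and 96.5% of replicated peaks had a q-value under 0.05. The lists covered 1.47% of the genome in replicate 1, 1.05% in replicate 2 and 1.24% for replicated peaks, with median widths of 274, 313 and 452 bp. No list gives read counts, so the depth is unknown and no interval for counting error can be given for a peak.

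Genes came from GENCODE release M21 (build GRCm38, the same as mm10) and sequence from the RefSeq copy of GRCm38.p6. All 21 chromosomes fitted the lengths of that build. Peaks on 19 autosomes, X and Y entered the comparisons. The background was 21938 protein-coding genes, and 408 of the 409 list genes were found by symbol. A gene was called marked when a replicated peak overlapped the 1 kb on either side of any of its TSSs, and its promoter height was that of the tallest such peak. Neighbouring genes can share a peak, and 6 of the 25 housekeeping genes and 3 of the 23 marked patterning genes did so with another protein-coding gene. Distal peaks were those that met no such window of any annotated gene of any kind, and they were counted within 50 kb of any TSS of a gene. Domains were made by joining replicated peaks and ranked by the length that peaks covered, and the 100 widest were compared with the lists. Motif windows reached 250 bp to either side of the summits of distal peaks, and flanks of the same width were taken 2 kb from the peak edges where they met no peak of any list.

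The 20 gene lists, the 21 motif consensus sequences, the tests and the alternatives were fixed before the data were examined. The lists were cerebellar granule lineage, Purkinje and GABAergic lineage, hindbrain patterning and anterior Hox, brainstem neuron identity, pan-neuronal, progenitor and radial glia, astrocyte, oligodendrocyte, Shh pathway, forebrain and midbrain regulators, posterior Hox, choroid plexus, endothelial, microglia, meninges, erythroid, liver, muscle, epidermal and housekeeping genes. Some genes stand in more than 1 list, such as Pax6, Mycn, Ccnd2, Otx2, Lmx1a, Cspg4, Nkx2-2 and Ttr. For each list the text names up to 4 members with the highest promoter peak, up to 4 with the most distal peaks, and the members without a promoter peak (all if 4 or fewer, otherwise the first 4 in list order). It also names the genes in or nearest to the 15 widest domains and nearest to the 10 tallest distal peaks. Where neither applies, the text says that names were chosen after their values were seen; in the Hox clusters every gene was looked at.

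List shares were tested with two-sided Fisher exact tests, distal counts with 10000 random lists of the same size, peak widths and heights with 10000 relabellings, and the overlap of the replicate lists with 100 shuffles within chromosomes. Adjustment was by Benjamini-Hochberg over the 20 lists or 21 motifs, with a threshold of 0.05. Each motif was set beside up to 20 shuffles of its consensus. Genes, peaks and windows are not independent replicates, so the p-values describe these lists and not the spread between animals. Intervals of shares are Wilson 95% intervals unless called exact. The alternatives fixed in advance were another promoter window (500 bp or 2.5 kb), the 5'-most TSS only, the upper 50% of the peaks by height, the pooled list, each replicate list alone, distal windows of 25 and 100 kb, marked genes only, flanks matched on G+C in bins of 2 percentage points, motif windows of 100 bp to either side, a joining distance of 5 kb, a ranking by fold enrichment times width, an overlap of at least 50% of both peaks, and equal numbers of the strongest peaks. Added after the data were seen were replicated peaks that overlap both replicate lists, distal counts at the 5'-most TSS only, and lists without members within 100 kb of an earlier member.

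The tests were checked on simulated data. With 20000 simulated genes, 97% of lists of 22 genes with a marked share of 90% were called and 5% of random lists, out of 100 each. For the distal counts, 100% of lists with 4 more distal peaks per gene were called and 8% of random lists, out of 100 each. Computation used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. Peaks on sequences outside the assembled chromosomes were left out of the comparisons.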

Results

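Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by ChIP-seq in the hindbrain of B6NCrl mouse embryos at embryonic day 16.5. At this age the hindbrain holds the growing cerebellum and the brainstem. The series has 1 group of 2 biological replicates, and each replicate is a pool of hindbrains from male and female embryos. Replicate 2 pooled 37 embryos, and the labels give no number for replicate 1. The labels name no second tissue, stage or treatment. The comparisons are therefore between the replicates, between promoters and distal sites, and between gene groups within the tissue. The deposited lists held 86863 peaks for replicate 1, 56767 for replicate 2, 65937 for the pooled data and 49032 replicated peaks, all on mouse build mm10. The files hold no read counts, so the depth of each replicate is unknown. A peak's height is the fold enrichment that came with the deposited list.

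The most strongly acetylated sites of the hindbrain were found in both replicates. The tallest replicated peaks, named here after their values were seen, lay at the promoters of the transcription factor genes Klf7 (fold enrichment 72.9, chromosome 1, 64117670 to 64122812) and Sp3 (61.7), of the arrestin gene Arrdc3 (66.7), of the histone methyltransferase gene Kmt5b (61.9), of Gm10762 (61.2) and of the actin gene Actb (60.4). In the replicate 2 list Klf7 stood at 42.5 and Kmt5b at 38.5. Of the 10% of peaks with the highest fold enrichment, the other replicate overlapped 99.95% in replicate 1 and 100% in replicate 2. Weak sites were shared far less often. In the lowest 10% the shares were 21.1% for replicate 1 and 54.0% for replicate 2. Over all heights, replicate 2 overlapped 45.9% of the replicate 1 peaks and replicate 1 overlapped 74.2% of the replicate 2 peaks, by at least 1 bp. Shuffled lists gave 2.22% and 3.05%, and none of 100 shuffles reached the observed shares (permutation p = 0.0099 for each, the smallest the shuffles can give). Across 42088 overlapping peaks, the heights correlated with a Spearman rho of 0.652 and a Pearson r of 0.738 on the log2 scale. Peaks are not independent replicates, so these values describe the lists only. Replicate 1 had 1.53 times as many peaks as replicate 2, and with an overlap of at least 50% of both peaks the shared portions fell to 29.0% and 44.3%. Among the 28380 strongest peaks of each list by p-value, overlapping by at least 1 bp, they were 72.4% for replicate 1 and 77.8% for replicate 2.

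**Figure D1:**
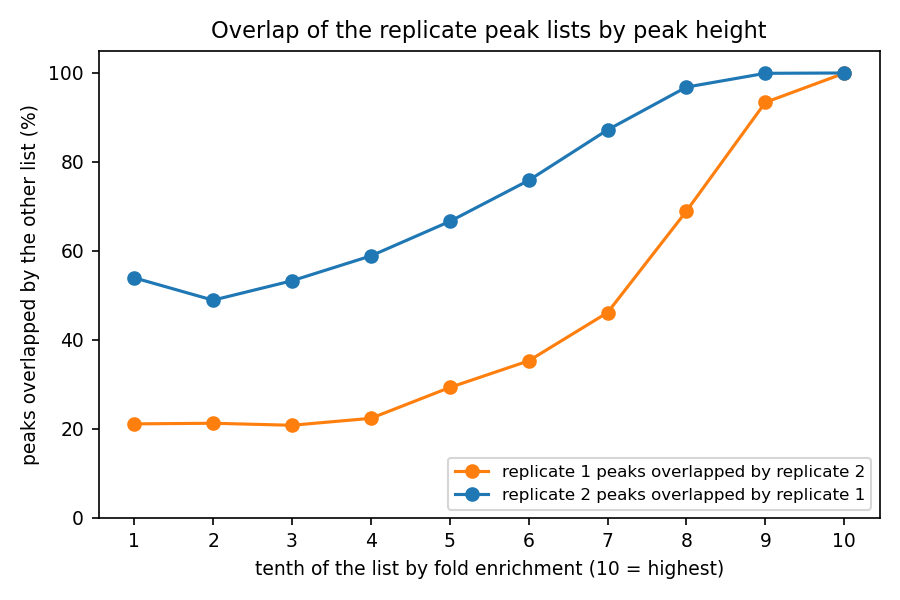
Share of peaks in each replicate list that the other list overlaps by at least 1 bp (vertical axis, %), in steps of 10% of the list by fold enrichment (horizontal axis, 10 = highest). In the highest step the shares were 99.95% for replicate 1 and 100% for replicate 2, and in the lowest 21.1% and 54.0%.

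Most protein-coding genes carried the mark at their promoters. Of 21938 protein-coding genes, 12391 (56.5%, Wilson 95% interval 55.8 to 57.1%) had a replicated peak within 1 kb of an annotated transcription start site (TSS). The share was 58.4% in the replicate 1 list and 56.8% in the replicate 2 list (SD 1.18 points, n = 2). Both lists marked 12124 promoters, replicate 1 alone 697 and replicate 2 alone 331.

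Neuronal and progenitor genes stood out above this level. All 25 pan-neuronal genes were marked, among them Dpysl3 (fold enrichment 31.7), which guides axon growth, the neuronal repressor gene Myt1l (28.5), the RNA-binding protein gene Celf4 (27.9) and Mapt (24.7), which encodes the tau protein. Of 25 progenitor and radial glia genes, 24 (96.0%) were marked, led by Nfib (32.7), a factor needed for glial and cerebellar development, the RNA-binding protein genes Msi1 (31.3) and Msi2 (23.3), and the Notch ligand gene Dll1 (22.5). Some of these heights differed between the lists of replicates 1 and 2, with 34.2 and 17.7 for Myt1l, 16.0 and 24.1 for Celf4, 23.6 and 16.4 for Mapt and 13.4 and 25.7 for Msi2. The exception was the proliferation marker Mki67, which had weak peaks in the replicate 1 list (3.92) and the replicate 2 list (3.76) and none among the replicated peaks. The 25 housekeeping genes were all marked as well, with Actb at 60.4, Ywhaz at 50.8, Eef1a1 at 39.7 and Hmbs at 33.7. Against all other genes, of which about 56.4% were marked, the adjusted exact p was 7.43e-06 for the pan-neuronal and the housekeeping genes and 7.08e-05 for the progenitor genes (Fisher exact tests, two-sided, Benjamini-Hochberg over the 20 lists).

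Genes of the cerebellum and of hindbrain patterning were also marked in most cases. In the granule cell lineage, which forms the most numerous neurons of the cerebellum, 20 of 22 genes (90.9%, adjusted exact p = 0.00135) were marked. The homeobox gene Meis1 was the highest at 41.2, followed by Nhlh2 (21.8), Zic2 (19.9) and Zic4 (19.5), and the Zic1 promoter reached 19.2. Nhlh2 had a fold enrichment of 18.1 in the replicate 1 list and 3.98 in that of replicate 2, and Zic1 12.4 and 20.7. Neurod1 and Eomes were the unmarked members, although Neurod1 had peaks of 3.62 in the replicate 1 list and 3.67 in the replicate 2 list. Of 25 patterning and anterior Hox genes, 23 (92.0%, adjusted exact p = 0.000324) were marked, with Hoxb2 at 24.9, Hoxa2 at 23.7, and Hoxb3 and Hoxb4 at a shared peak of 15.6. Hoxb1 and Hoxd1 were not marked. Among 22 genes of Purkinje cells and other cerebellar GABAergic neurons, 17 (77.3%) were marked, a share that did not pass the test (adjusted exact p = 0.0636). It passed in each replicate list alone, where 81.8% were marked (adjusted exact p = 0.0253 in replicate 2 and 0.0491 in replicate 1). The nuclear receptor gene Rora (28.8), Ebf3 (21.5), Ebf1 (18.3) and Gad2 (18.4), which encodes a GABA-synthesising enzyme, led this group, although Ebf3 had only 14.1 in the replicate 2 list and Ebf1 only 10.6 in that of replicate 1. Ptf1a, Calb1, Pcp2 and Kirrel2 were without a replicated promoter peak.

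Glial and signalling genes were marked in part. Of 16 genes of the Sonic hedgehog (Shh) pathway, which drives granule cell precursors to divide, 14 (87.5%, adjusted exact p = 0.0176) were marked, among them the receptor gene Ptch1 (28.6, but 14.5 in the replicate 1 list), Mycn (17.6) and Boc (15.3). Sufu had a peak of 15.5 (10.1 in replicate 1) that it shared with the neighbouring gene Actr1a, and Hhip and Sfrp1 had none. Of 15 astrocyte genes, 13 (86.7%, adjusted exact p = 0.0267) were marked, with the glutamate transporter gene Slc1a2 at 19.7, the glutamine synthetase gene Glul at 16.0, Ndrg2 at 11.8 and Sparcl1 at 9.35, and without Aqp4 and Gjb6. Oligodendrocyte genes did not pass the test, with 9 of 18 marked (50%, adjusted exact p = 0.654). Their peaks were low, with Cnp at 8.12, Sox8 at 5.49, Mbp at 5.28 and Olig1 at 4.66, and the myelin genes Plp1, Mog and Mag had none. Brainstem neuron identity genes were marked in 9 of 24 cases (37.5%, adjusted exact p = 0.0735). Slc17a6, the vesicular glutamate transporter gene of brainstem neurons, was the highest at 16.1, followed by Lbx1 (10.4), the glycine transporter gene Slc6a5 (8.14) and Lmx1b (6.72), while the motor neuron regulator genes Phox2a, Phox2b, Isl1 and Tbx20 were unmarked. In the replicate 1 list alone 14 of the 24 brainstem genes (58.3%) were marked, about the share of all genes there, with 5 marked in replicate 1 only and 1 in replicate 2 only. In that list the Shh call was lost (81.3%, adjusted exact p = 0.110), as was the astrocyte call (86.7%, adjusted exact p = 0.0515). The astrocyte call was also lost with 1 TSS per gene (73.3%, adjusted exact p = 0.141) and in the upper 50% of the peaks by height (66.7%, adjusted exact p = 0.307).

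Regulators of other regions and genes of other tissues were mostly unmarked. None of 18 posterior Hox genes had a replicated promoter peak (adjusted exact p = 6.21e-06). Of 24 forebrain and midbrain regulators 4 were marked (16.7%, adjusted exact p = 0.000239), namely Bcl11b (14.7), Satb2 (9.01), Lhx2 (3.96) and Otx2 (2.42, with no peak in replicate 1 and 4.05 in replicate 2), and Foxg1, Emx1, Emx2 and Six3 were not. Liver genes were marked in 3 of 20 cases (15%, adjusted exact p = 0.000324), at Foxa3 (7.53, a peak shared with Sympk), Apoa1 (3.53) and Afp (3.38). Foxa3 had 3.26 in the replicate 1 list and 9.39 in that of replicate 2, and Apoa1 had no peak in replicate 1. Skeletal and cardiac muscle genes were marked in 2 of 20 cases (10%, adjusted exact p = 0.000104), at Mylpf (11.6, a peak shared with Tbc1d10b) and Myh7 (11.4). The Myh7 peak lay 19701 bp from the 5'-most TSS of the gene, at another annotated TSS and beside the microRNA gene Mir208b. Such distances also occurred in the neural lists, with 195400 bp at Nfib and 43994 bp at Dpysl3, while the Myt1l and Celf4 peaks covered that TSS. Epidermal genes were marked in 3 of 20 cases (15%, adjusted exact p = 0.000324), but those peaks were tall, with Lor at 23.8, Krt10 at 22.7 and Krt1 at 14.7, and present in both replicate lists. They lay over coding sequence away from the first TSS, by 815 bp at Lor (chromosome 3, 92080319 to 92082327), 2294 bp at Krt10 and 4258 bp at Krt1, and coding sequence made up 72.6%, 52.8% and 42.0% of them. Their position was looked at after their heights were seen, and the peak lists alone do not show whether they are acetylated sites or artefacts of the sequence there. The other keratin genes of the list, Krt5, Krt14 and Krt15, and the epidermal regulator gene Trp63 had no replicated promoter peak. With the 5'-most TSS alone the marked shares were 8.33% for forebrain and midbrain, 5.0% for liver and 5.0% for epidermal genes, and 2 of the 18 posterior Hox genes (11.1%) were marked in the replicate 1 list.

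Cell types that surround or enter the hindbrain were marked to different degrees. Endothelial genes were marked in 10 of 20 cases (50%, adjusted exact p = 0.654), at low heights such as Eng (4.95), Emcn (4.57), Mfsd2a (4.20) and Egfl7 (4.10), and Pecam1, Cdh5, Tek and Flt1 were unmarked. Choroid plexus genes were marked in 5 of 16 cases (31.3%, adjusted exact p = 0.0582), with the ciliogenesis regulator gene Foxj1 at 10.97, Enpp2 at 8.62, Calml4 at 3.49 and Kl at 3.47, and none at Ttr, the main secretory product gene of the choroid plexus. Meningeal, mesenchymal and pericyte genes were marked in 6 of 20 cases (30%, adjusted exact p = 0.0299), with Foxc1 at 6.05, Pdgfrb at 4.38, Tbx18 at 4.01 and Prrx1 at 3.63. Microglia and macrophage genes were marked in 1 of 18 cases (5.56%, adjusted exact p = 3.79e-05), C1qb at 3.19, and erythroid genes in 1 of 15 cases (6.67%, adjusted exact p = 0.000221), Tal1 at 5.45. Emcn and C1qb had no promoter peak in the replicate 2 list. More of these promoters were marked in replicate 1 alone than in replicate 2 alone, with 7 against 1 endothelial genes, 3 against 1 choroid plexus genes, 4 against 0 meningeal genes and 3 against 0 microglial genes. Forebrain and midbrain regulators had 6 against 1, while liver genes had 0 against 2 and epidermal genes 0 against 1. All genes had 697 against 331, and over the lists of other regions, cell types and tissues together the difference from other genes did not pass the test (Fisher exact p = 0.0528). In the replicate 1 list 8 of 16 choroid plexus genes (50%) were marked. In the replicate 1 list alone the calls of the forebrain and midbrain regulators (41.7%, adjusted exact p = 0.135) and of the meningeal genes (55%, adjusted exact p = 0.865) were lost, and in the replicate 2 list alone the meningeal call was lost as well (35.0%, adjusted exact p = 0.0859). Microglial (22.2%) and erythroid genes (13.3%) kept theirs in replicate 1, and in the upper 50% of the peaks by height endothelial genes were also below other genes (10%, adjusted exact p = 0.000327), as were choroid plexus genes (2 of 16, adjusted exact p = 0.00249).

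**Figure D2:**
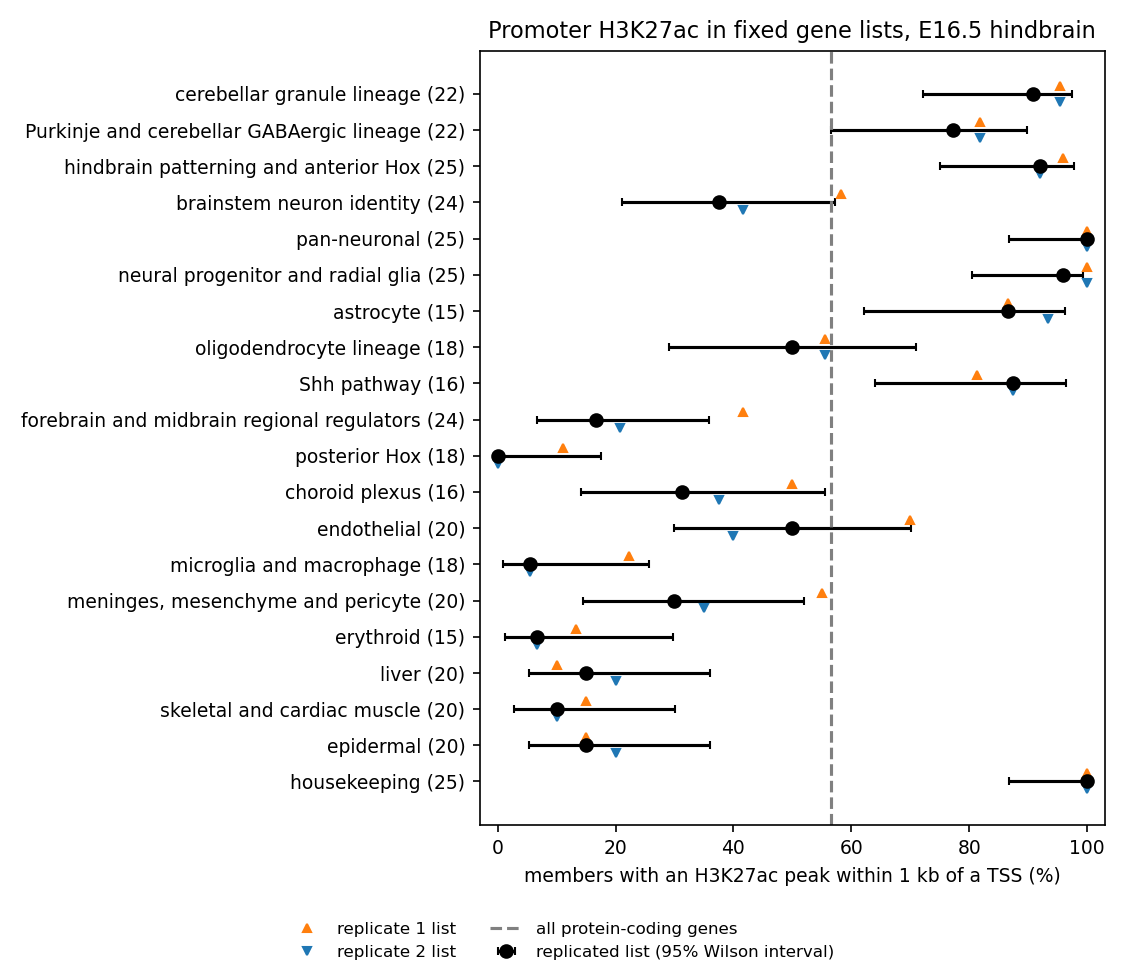
Share of each fixed gene list with an H3K27ac peak within 1 kb of a TSS (horizontal axis, %; members in parentheses). Black points and bars give the replicated list with its 95% Wilson interval, orange and blue triangles the replicate 1 and replicate 2 lists, and the dashed line all protein-coding genes (56.5%); the pan-neuronal and housekeeping lists reached 100% and the posterior Hox list 0.

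The Hox clusters, whose genes are ordered along the chromosome as their domains are along the body, were acetylated at their anterior ends. In the Hoxa cluster all 5 genes of paralog groups 1 to 5 were marked, both genes of groups 6 to 8 and none of the 4 of groups 9 to 13. In the Hoxb cluster 4 of 5, 3 of 3 and 0 of 2 were marked. In the Hoxc cluster the counts were 2 of 2, 1 of 2 and 0 of 5, and in the Hoxd cluster 2 of 3, 0 of 1 and 0 of 5. Hoxb2 (chromosome 11, 96350525 to 96354012) and Hoxa2 (chromosome 6, 52162417 to 52164831), which pattern the rhombomeres, had the highest peaks among Hox genes in the replicated list, with Hoxb2 at 23.5 and 20.7 and Hoxa2 at 19.6 and 24.6 in the lists of replicates 1 and 2. In the replicate 2 list Hoxb3 (21.2) was above Hoxb2. In groups 6 to 8 heights were low in the Hoxa and Hoxc clusters, at 4.22 for Hoxa6, 3.58 for Hoxa7 and 3.93 for Hoxc6. In the Hoxb cluster they were below those of Hoxb2 to Hoxb5, but rose from 6.28 at Hoxb6 to 8.34 at Hoxb7 and 10.1 at Hoxb8. No trend was tested. Hoxa7 had no peak in the replicate 2 list, and Hoxb9 (3.26), Hoxd1 (4.22) and Hoxd9 (3.59) had a weak peak in the replicate 1 list only. Counted at the 5'-most TSS alone, Hoxa7, Hoxc5 and Hoxc6 were unmarked.

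**Figure D3:**
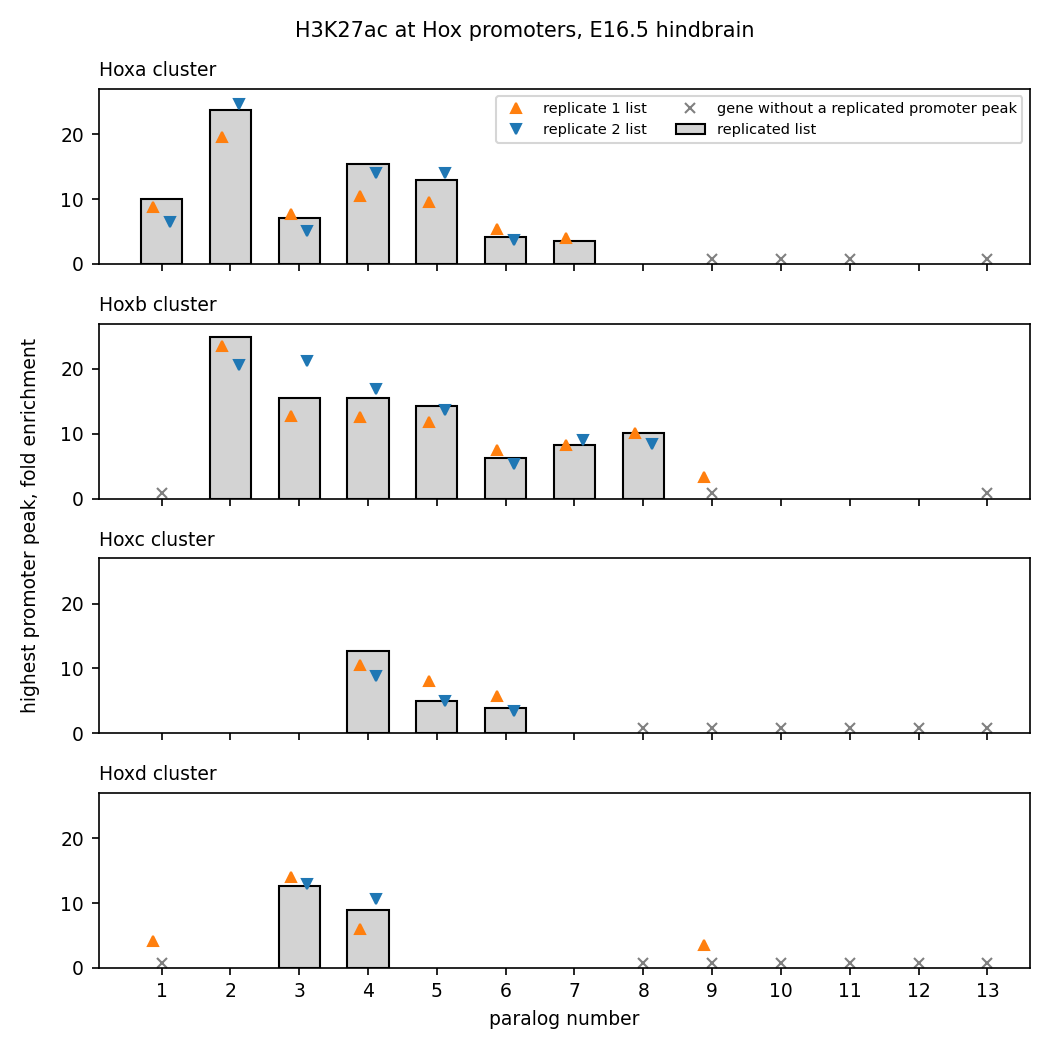
Highest promoter peak (vertical axis, fold enrichment) of each Hox gene by paralog number (horizontal axis) in the 4 clusters; bars are the replicated list, triangles the lists of replicates 1 and 2, and crosses genes without a replicated promoter peak. No gene of groups 9 to 13 had a replicated promoter peak.

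Promoters carried wider and taller peaks than distal sites. Of the replicated peaks on the chromosomes, 20540 (41.9%) lay within 1 kb of a TSS and 28483 did not. The median promoter peak was 668 bp wide with a fold enrichment of 7.31, and the median distal peak was 365 bp wide with 3.89, ratios of 1.83 and 1.88. Introns held 17688 peaks (36.1%), intergenic sequence 9073 (18.5%) and exons outside promoters 1722 (3.51%). Promoters made up 94.3% of the tallest 10% of peaks and 19.5% of the lowest 10%. The tallest distal peak (42.5, chromosome 7, 73616081 to 73619738) lay 76.4 kb from Chd2, which encodes a chromatin remodeller, and the next at 5.99 kb from Zfp869 (41.1) and 6.98 kb from Anp32e (37.9). Another lay 46.6 kb from Lsamp (36.9), a neuronal adhesion gene, and one 60.6 kb from Irf2bpl (34.9). The Hacl1 peak (36.1) covered an exon of Btd, and the remaining 4 of the 10 tallest lay near Ubc (34.5), Ndufa4l2 (32.1), Tex44 (31.5) and Snx10 (31.4). All 10 were present in both replicate lists, although the Ubc peak had only 22.7 in replicate 2 and the Ndufa4l2 peak only 19.7 in replicate 1. Permutation tests with 10000 relabellings of the peaks gave p = 0.0001 for width and for height, the smallest they can give. Peaks at promoters made up 30.2% of the longer replicate 1 list and 41.2% of the replicate 2 list.

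Genes of the progenitor, pan-neuronal, cerebellar and patterning lists were surrounded by several times more distal peaks than other genes. Within 50 kb of a TSS, protein-coding genes had 1.77 distal peaks on average, and 52.9% had none. Since any TSS counts, a gene with TSSs far apart is searched over a longer stretch, and genes were not matched for this. Progenitor and radial glia genes had 10 ± 12.7 (SD over 25 genes), with 57 at Msi2, 31 at Notch1, 30 at Nfia and 18 at Nfib. Pan-neuronal genes had 8.60 ± 11.9, with 57 at Rbfox3, which encodes the neuronal marker NeuN, 26 at Myt1l, 18 at Celf4 and 14 at Cplx2. In the lists of replicates 1 and 2, Rbfox3 had 90 and 61, Myt1l 51 and 37, and Celf4 37 and 21. Genes of the Purkinje and GABAergic lineage had 8.55 ± 13.8, with 67 at Ebf3 (chromosome 7, 137193673 to 137314445), 14 at Lhx1, 13 at Lhx5 and 11 at Pax2. Granule lineage genes had 8.46 ± 7.58, with 30 at Meis2, 17 each at Zic4 and Neurod2 and 16 at Zic1. Patterning and anterior Hox genes had 6.84 ± 4.69, with 16 at Hoxb3 and Hoxb4, 14 at Hoxb5 and 12 at Pax3. Shh pathway genes had 5.38 ± 10.5, of which Sufu had 42 and Boc 14.

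Other groups had distal peaks within the range of random lists, or, for epidermal genes, below it. Astrocyte genes had 3.93 on average, with 17 at Aldh1l1 and 11 at Fgfr3, oligodendrocyte genes 3.50, with 11 at Sox8, and posterior Hox genes 3.33, with 14 at Hoxb9 beside the marked part of its cluster. Microglial genes had 2.56, with 9 at the unmarked receptor gene Csf1r, and housekeeping genes 2.36. The means were 2.00 for muscle, 1.85 for endothelial, 1.71 for brainstem, 1.56 for choroid plexus, 1.5 for meningeal, 1.47 for erythroid, 1.20 for liver and 0.792 for forebrain and midbrain genes, although Bcl11b of that last group had 12. The pericyte gene Pdgfrb also had 12, but it is a neighbour of Csf1r and their windows overlap. Epidermal genes had 0.10. The granule, Purkinje, patterning, pan-neuronal and progenitor lists lay above 10000 random lists of the same size and the epidermal list below them (two-sided permutation p = 0.0002 for each, the smallest the draws can give, adjusted permutation p = 0.000667 over 20 lists). The Shh list passed too, with a mean above most but not all random lists (permutation p = 0.0056, adjusted permutation p = 0.0160). Its median was only 2, however, and Sufu alone held 42 of its 86 distal peaks, so its mean rests largely on 1 gene. The others did not pass, with adjusted permutation p from 0.142 for astrocyte to 0.980 for brainstem genes. The Shh call was lost among marked genes alone (6, adjusted permutation p = 0.0538) and with the upper 50% of the peaks by height (1.56, adjusted permutation p = 0.0964), and the epidermal call among its 3 marked genes. In the longer replicate 1 list the means of the lists that did not pass also rose, to 4.25 for brainstem, 4.60 for endothelial, 2.0 for forebrain and midbrain, 3.38 for choroid plexus and 7.11 for posterior Hox genes, and that of epidermal genes to 0.70 (0.25 in replicate 2). The 6 raised means there were 13.8 for granule, 14.4 for Purkinje, 11.8 for patterning, 15.8 for pan-neuronal, 15.3 for progenitor and 8.44 for Shh genes. Patterning genes had 10.4 in replicate 2. With 1 TSS per gene, chosen after the data were seen, the pan-neuronal mean fell to 3.16 and the progenitor mean to 6.28. The Purkinje mean fell to 5.32 and the Shh mean to 3.38, and each still passed above random lists.

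**Figure D4:**
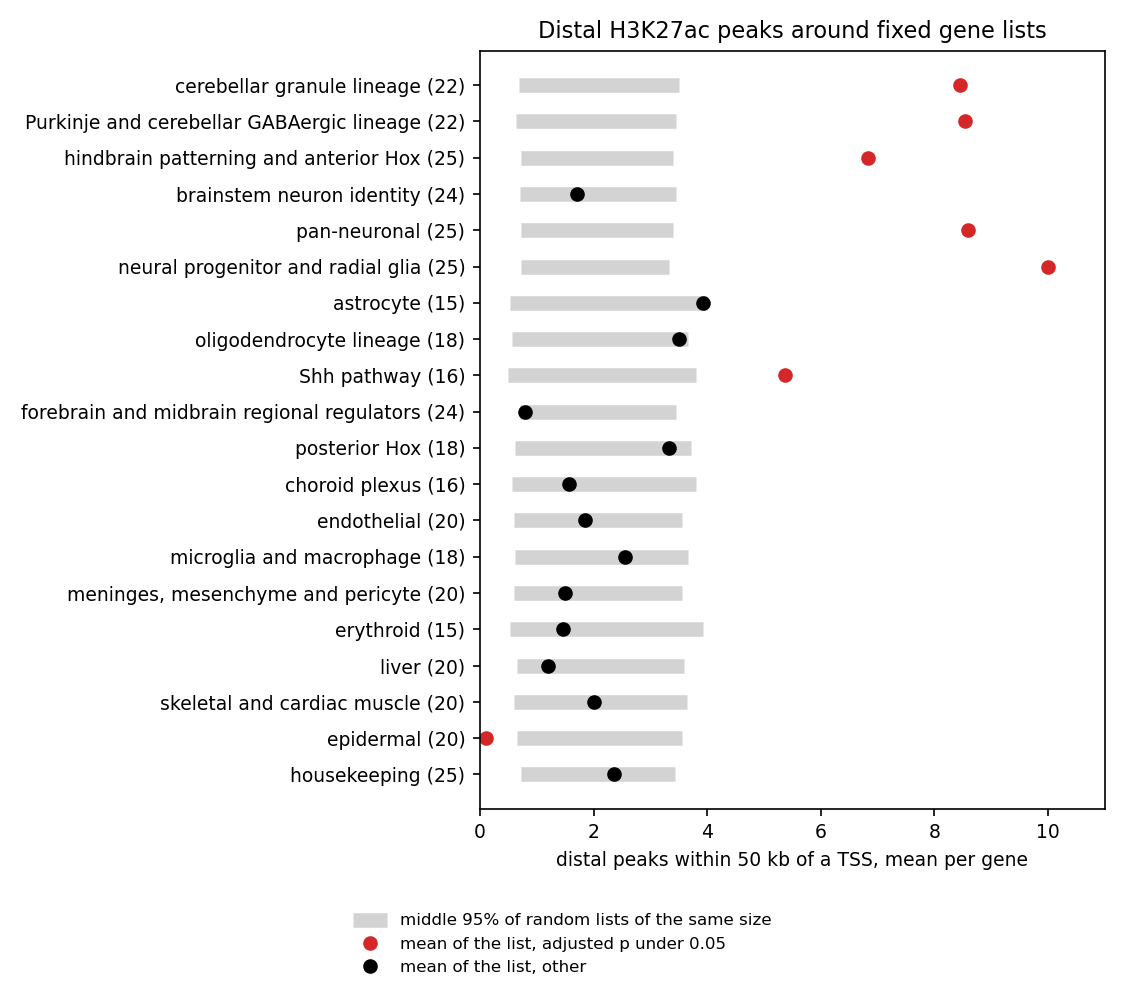
Mean number of distal H3K27ac peaks per gene within 50 kb of a TSS (horizontal axis) for each fixed list (members in parentheses), with the middle 95% of random lists of the same size in grey. Red points have an adjusted p under 0.05: 6 lists from 5.38 (Shh pathway) to 10 (progenitor) lie above the grey range and the epidermal list (0.10) below it.

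The widest acetylated domains covered progenitor regulators, Hox clusters and Zic genes. Peaks were joined over the gap customary for stitching acetylation peaks into super-enhancers, which gave 21270 domains. The widest covered 96.6 kb of a 346.5 kb span at Msi2 (chromosome 11, 88373092 to 88719567). It was followed by a domain of 66.7 kb with Ntmt1, Cstad and 1700001O22Rik, by Hoxb2 to Hoxb8, where 63.7 kb of 82.6 kb were covered, and by an intergenic domain of 57.1 kb whose nearest protein-coding gene is Rhcg and which holds the microRNA gene Mir9-3. Then came Ebf3 with 52.1 kb, the corepressor gene Ncor2 with 51.1 kb and Gse1 with 50.4 kb. An intergenic domain near Rhbg (42.2 kb) holds Mir9-1, and one near Ppara (39.3 kb) holds Mirlet7b. The rest of the first 15 covered Ahdc1 and Wasf2 (41.0 kb), Hoxa2 to Hoxa6 (37.2 kb), Cxxc5 (36.0 kb), Zic1 and Zic4 (35.1 kb), Myo18a, Pipox and Sez6 (33.6 kb), and Trak1 and Ulk4 (32.2 kb). Among the 100 widest domains, patterning genes had 10 of 25 members inside (Hoxa2 to Hoxa5, Hoxb2 to Hoxb5, Hoxd3 and Hoxd4; adjusted exact p = 8.81e-14), granule genes 6 of 22 (Meis1, Meis2, Zic1, Zic2, Zic4 and Zic5; adjusted exact p = 2.28e-07) and progenitor genes 4 of 25 (Msi2, Nfib, Notch1 and Sox2; adjusted exact p = 0.000367), against about 0.82% of other genes (Fisher exact tests, two-sided). Purkinje genes had 2 inside (Ebf3 and Lhx5, adjusted exact p = 0.0739), pan-neuronal genes 2 (Myt1l and Rbfox3, adjusted exact p = 0.0755), and the other 15 lists had none. Neighbouring Hox or Zic genes share a domain, so their counts are not independent. With members near an earlier member of the list left out no patterning gene lay inside. That choice keeps the first gene of each cluster, such as Hoxb1, and leaves out the others, although the domains of Hoxb2 to Hoxb8 and Hoxa2 to Hoxa6 are among the widest. Ranked by fold enrichment times width, 59 of the 100 domains were the same, and the progenitor call was lost (2 members, adjusted exact p = 0.124).

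Binding sites of several neural transcription factors were more common around distal summits than beside the peaks. The site of RFX factors, which drive genes of cilia, was found in 0.365% of windows at distal summits and in 0.0424% of flanking windows (8.62-fold, adjusted exact p = 3.29e-24). The palindrome of the nuclear factor I (NFI) family, to which Nfia and Nfib belong, was found in 0.962% against 0.221% (4.35-fold, adjusted exact p = 4.49e-40). The ZIC site was found in 23.1% against 13.95% (1.65-fold, adjusted exact p = 1.00e-209), the MEF2 site in 1.16% against 0.753% (1.54-fold), the ROR site in 0.586% against 0.403% (1.46-fold) and the SOX site in 12.3% against 9.06% (1.36-fold). The POU octamer reached 1.19-fold, the E-box with a CAGCTG core 1.46-fold and the proneural E-box of Atoh1 and Neurod factors 1.24-fold. Sites classed in advance as those of other lineages were less common at the peaks, with GATA at 0.847-fold, RUNX at 0.808-fold and HNF4 at 0.747-fold. HNF1, of the same class, did not pass the test (0.839-fold, adjusted exact p = 0.881). For GATA the class is loose, since Gata2 and Gata3 stand in the brainstem list and had promoter peaks of 3.64 and 4.01. The folds of GATA, RUNX, HNF4 and HNF1, and those of both E-boxes, lay within the range of shuffled forms of the same consensus. For EBF and NRF1 11 of 20 shuffled forms were as high as the site itself, and for ETS 9 of 20. The homeodomain site (0.972-fold, adjusted exact p = 0.187) did not pass the test, yet lay above all its shuffled forms (up to 0.885). The HOX-PBX site was slightly less common (0.908-fold, adjusted exact p = 0.00467), but within the range of its own (up to 0.943).

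Distal peaks were richer in G+C than their flanks, at 49.9% against 45.5%, and flanks matched on G+C changed part of the picture. RFX (7.17-fold), NFI (2.86), MEF2 (2.40), POU (1.63), ROR (1.56), SOX (1.40) and ZIC (1.24) remained above 1 and above every shuffled form of their own consensus. Homeodomain (1.51) and HOX-PBX sites (1.29) turned to above 1, and the EBF site, at 1.32-fold against all flanks, turned to 0.897-fold (adjusted exact p = 0.186). Among general factors CTCF (2.65-fold, 1.90 when matched) stayed above 1, ETS (1.58, 1.16) and NRF1 (3.30, 1.75) lost their calls, TEAD (1.01, 1.09) did not pass in either, and AP-1 (0.960, adjusted exact p = 0.130) passed as less common only when matched (0.915, adjusted exact p = 0.00451). The E-boxes (1.20 and 1.12) stayed above 1 but within the range of their shuffled forms, and GATA (0.974, adjusted exact p = 0.497) lost its call. RUNX (0.887) and HNF4 (0.803, adjusted exact p = 0.0101) still passed as less common, and HNF1 (2-fold, adjusted exact p = 0.407) did not pass. The tests were two-sided Fisher exact tests on 28480 peak windows and 42473 flanking windows, or 24014 of each when matched on G+C, that reached 250 bp to either side of their middle, with Benjamini-Hochberg adjustment over 21 motifs. Of the 13 motifs that passed above 1 against all flanks, 4 lost their calls within 100 bp of the summit and turned to below 1, with folds of 0.470 for RFX, 0.907 for POU, 0.983 for MEF2 and 0.992 for CTCF, and ROR (1.09), ETS (1.35) and NRF1 (1.12) lost theirs too. The other 6 passed there as well, namely NFI (3.60), ZIC (1.93), the E-box with a CAGCTG core (1.54), SOX (1.38), EBF (1.36) and the proneural E-box (1.16). These narrower windows held 51.87% G+C against 45.55% in their flanks and were not matched on G+C. Base composition may therefore have shifted these folds, as it did for EBF in the wider windows.

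**Figure D5:**
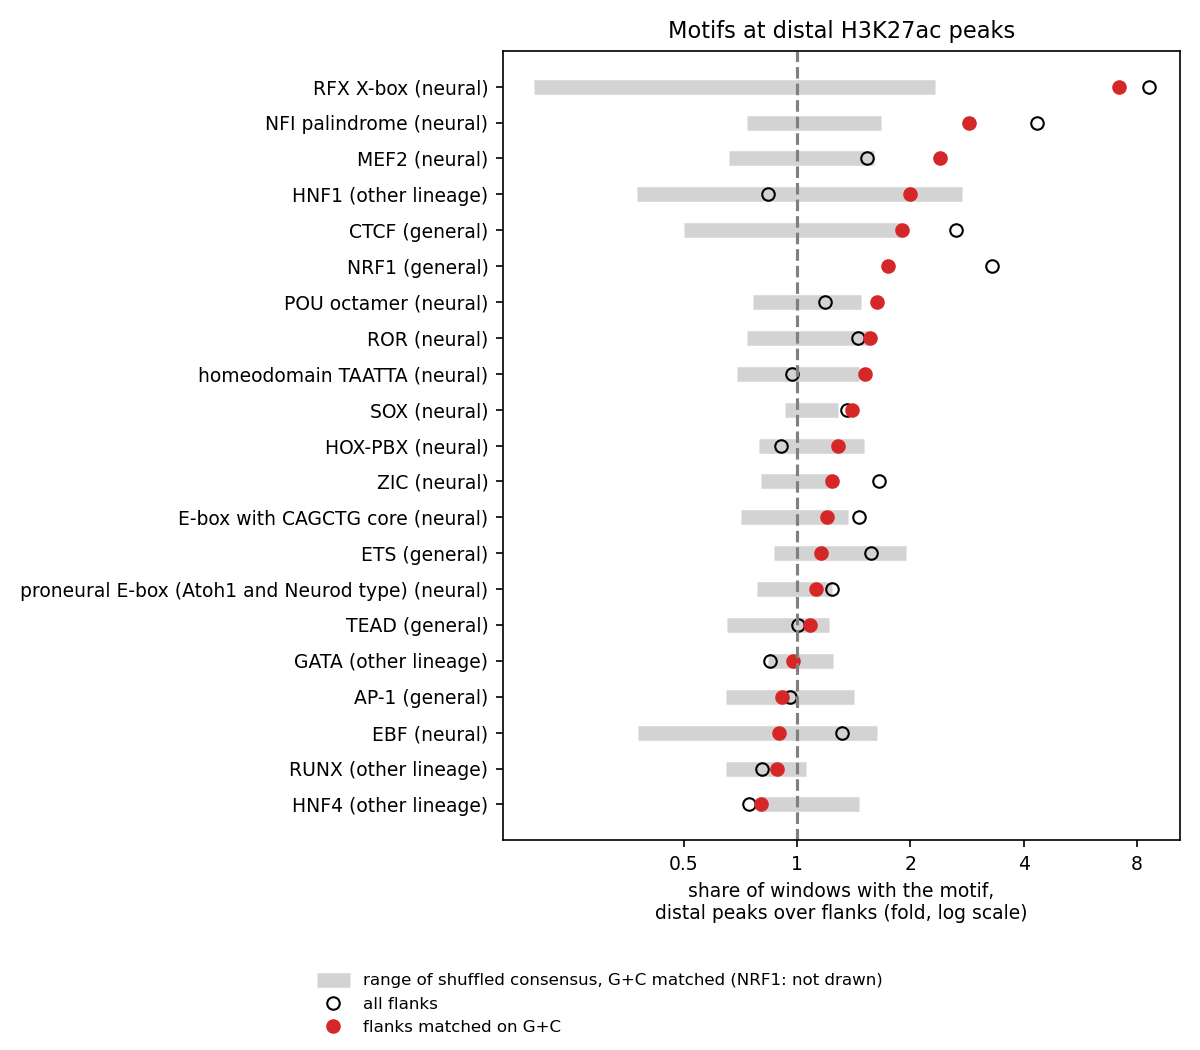
Share of windows with each motif at distal peaks over that of flanking windows (horizontal axis, fold, log scale), against all flanks (open circles) and flanks matched on G+C (red), with the range of shuffled forms of the consensus against matched flanks in grey (not drawn for NRF1, whose range has no finite bounds). RFX (7.17) and NFI (2.86) lie farthest above their shuffled forms.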

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

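The count in this part was looked at only after the data were seen, and no test was run on it. In sequence that no comparison used, 9 replicated peaks lay on unplaced or unlocalised sequences outside the assembled chromosomes. They are given because no comparison covers that sequence, and nothing here sets how many peaks to expect on it. The highest had a fold enrichment of 18.1, on an unlocalised sequence of chromosome 4 that held 3 of the 9 peaks.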

How the results depend on the processing

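Tests with replicated peaks that overlap both replicate lists, with distal counts at the 5'-most TSS and with neighbouring members left out were chosen only after the results were seen. No paired analysis was possible because the series has 1 group. Of 675 values recomputed under an alternative, 603 were counted as the same. Those with a test kept their direction and their side of the threshold, or passed in neither setting, whatever their direction. Those without a test stayed close in value or within the replicate spread. Of the rest, 26 newly passed the threshold, 25 no longer passed it, 12 moved and 9 reversed with a pass in at least 1 setting. The called promoter shares of the granule, patterning, pan-neuronal, progenitor, posterior Hox, microglia, erythroid, liver, muscle, epidermal and housekeeping genes kept their calls under every alternative run. The share of marked genes was 52.7% with the 5'-most TSS, 57.8% with 2.5 kb windows, 51.8% with the upper 50% of the peaks, 58.1% with the pooled list and 54.4% with peaks in both lists. The astrocyte share was 73.3% with the 5'-most TSS, 80% with 500 bp windows, 66.7% in the upper 50% and 80% with peaks in both lists, none of which passed. The meningeal share was 30% with the 5'-most TSS and 35% with 2.5 kb windows or the pooled list, none of which passed. The Purkinje share passed at 81.8% with 2.5 kb windows and with the pooled list. Newly below other genes were the brainstem genes at 33.3% with 500 bp windows, 29.2% in the upper 50% and 33.3% with peaks in both lists, the choroid plexus genes at 25%, 12% (2 of 16) and 25%, and the endothelial genes at 10% in the upper 50% and 30% with peaks in both lists. Leaving out each replicate gave ranges of 56.8 to 58.4% for all genes, 81.8 to 81.8% for Purkinje, 81.3 to 87.5% for Shh, 86.7 to 93.3% for astrocyte, 20.8 to 41.7% for forebrain and midbrain and 35 to 55% for meningeal genes, and, with no call in either, 41.7 to 58.3% for brainstem, 37.5 to 50% for choroid plexus and 40 to 70% for endothelial genes, 30.2 to 41.2% of peaks at promoters, and 0 to 2 Shh genes in the widest domains. With peaks in both lists 49.8% lay at promoters. The rank correlation of heights was 0.817 with an overlap of at least 50% of both peaks. For distal counts, Shh genes did not pass at 6 among marked genes or at 1.56 in the upper 50%. Among marked genes the epidermal mean was 0 over 3 genes and 0 lists lay below random lists, and posterior Hox, microglia and erythroid genes had too few marked members for a value. Newly above random lists with the 5'-most TSS were astrocyte genes at 3.67, oligodendrocyte genes at 3.17 and posterior Hox genes at 3.17, the last also at 6.94 within 100 kb and at 8.50 with neighbouring members left out. In the last setting only Hoxa9, Hoxb9, Hoxc8 and Hoxd8 were kept, the members nearest the marked part of each cluster. Members without distal peaks, such as Hoxa13 and Hoxd13, were left out, so that rise comes from the choice of members. With neighbouring members left out 0 patterning genes lay in the widest domains, since that choice keeps the first gene of each cluster and leaves out the others. Ranked by fold enrichment times width, 59 of the 100 domains were shared. Matched on G+C, the EBF fold was 0.897, the HOX-PBX fold 1.29 and the homeodomain fold 1.51. Within 100 bp of the summit 6 motifs passed above flanks in place of 13, with folds of 0.992 for CTCF, 0.983 for MEF2, 0.907 for POU and 0.470 for RFX. Those flanks were not matched on G+C. Apart from neighbouring members, few marked genes and base composition, the cause was not tested. Since the depth is unknown, a promoter without a peak cannot be called free of the mark.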

Other observations

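The microRNA groups and gene families below, and the tests of gene density on chromosome X, of base composition and of gaps for the HOX-PBX site, were chosen only after the results were seen. MicroRNA genes of the nervous system lay in some of the widest acetylated domains. All 3 genes of the neural microRNA Mir9 were among the 100 widest domains, Mir9-3 in a domain with 57.1 kb covered, Mir9-1 with 42.2 kb and Mir9-2 with 30.4 kb, each in sequence without a protein-coding TSS. Of the 3 genes of the neuronal microRNA Mir124, 2 were there (Mir124a-1 with 19.5 kb and Mir124a-2 with 15.4 kb), and the other lay in a narrower domain. The widest domains also held 2 of 11 let-7 genes, Mirlet7b and Mirlet7c-2 (39.3 kb), while 7 of the 11 lay in no domain at all. They held Mir125b-1 (25.9 kb) as well, and the Hox cluster genes Mir10a (63.7 kb) and Mir10b (19.5 kb). In all, 34 of 2202 microRNA genes lay in them. None of the 7 genes of the muscle microRNAs Mir1, Mir133 and Mir206, of the 3 genes of Mir196, which lie in the Hox clusters, or the gene of the liver microRNA Mir122 lay in any acetylated domain, but only 343 of the 2202 microRNA genes (15.6%) did, so this does not set them apart. All 4 Mir219 genes and 1 of 2 Mir128 genes lay in a domain outside the widest.

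Gene families differed in the same tissue. The sensory receptor families were almost wholly unmarked, with 1 of 1135 olfactory receptor genes (0.0881%, Olfr94) and 1 of 329 vomeronasal receptor genes (0.304%, Vmn1r4) carrying a promoter peak. So were the defensins (0 of 64) and the keratin-associated proteins (1 of 57). Ribosomal protein genes (73 of 76, 96.1%), histone genes (56 of 67, 83.6%) and genes named Zfp, which encode zinc finger proteins (316 of 394, 80.2%, adjusted exact p = 6.19e-23), were above other genes. Among the clustered protocadherins, which give neurons individual surface identities, 1 of 14 alpha genes (Pcdhac2), 0 of 22 beta genes (adjusted exact p = 2.38e-08) and 6 of 21 gamma genes (28.6%, adjusted exact p = 0.0206) were marked, the last including Pcdhgc3, Pcdhgc4 and Pcdhgc5. Sox genes (15 of 19, adjusted exact p = 0.0852) and solute carrier genes (215 of 371, adjusted exact p = 0.735) did not pass the test, nor did the LIM homeobox (4 of 8), Irx (4 of 6) and Fox genes (23 of 44; adjusted exact p = 0.735 for each). The tests were two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 15 families.

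Promoters of genes of other regions, cell types and tissues were marked in replicate 1 alone 27 times and in replicate 2 alone 5 times (84.4% of 32), against 67.3% for other genes (Fisher exact p = 0.0528). With the replicate 1 list shortened to the strongest 56760 peaks, as many as replicate 2 has, the share was 58.3% (14 against 10, exact 95% interval 36.6 to 77.9%), but other genes fell to 38.1% as well (Fisher exact p = 0.0552). Shortening the list lowers this share for any genes, so its fall decides nothing, and the length of the list and more cells of such types in replicate 1 both remain open. For members marked in both lists, the rank in replicate 1 minus that in replicate 2 was compared with that of genes of the same replicated height. It was 1.99 percentile points higher on average (27 genes, permutation p = 0.373), within the random range of -4.58 to 4.44. The labels name no difference in tissue or stage between the replicates, so no biological explanation from the design was tested. A difference in their controls, which the notes with the files leave possible, was not tested either.

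Chromosome X held 4.89 replicated peaks per Mb, against 14.1 to 34.1 on the autosomes. A low density of genes on X is not enough, since X also had 0.883 peaks per protein-coding gene, below the autosomes' 1.60 to 3.32. A low number of active genes remains open, since fewer X promoters were marked (40.6% of 948 against 57.7%). Marked X genes had 0.252 times as many distal peaks around them as marked autosomal genes (95% interval 0.200 to 0.307). That ratio cannot decide the question, since the count around a gene takes in distal peaks of its neighbours. These would also be fewer if few X genes were active. A candidate explanation is that fewer X copies are active per cell than autosomal copies in a pool of both sexes, since the median promoter height of marked genes on X was 0.784 times that on autosomes (9.38 against 12.0, 95% interval 0.722 to 0.829), and 0.818 and 0.736 times in the lists of replicates 1 and 2. How well reads map to X and the control signal there were not tested, so this stays a hypothesis.

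Homeodomain and HOX-PBX sites were no more common at distal summits than in flanks, although 13 of 15 Hox genes of paralog groups 1 to 5 and the genes Meis1 and Meis2 were marked. Base composition may account for this, since against flanks matched on G+C the homeodomain fold was 1.51, above the highest of 13 shuffled forms (1.46), and the HOX-PBX fold was 1.29 (adjusted exact p = 2.75e-09), though within the range of its shuffled forms (up to 1.51). Homeodomain sites may also lie between adjacent acetylated peaks, since they were 3.29 times as common in 3820 gaps as at the 7116 summits beside them, slightly above every shuffled form (2.33 to 3.13). The gaps were poorer in G+C than the summits (45.55% against 51.61%), and this comparison was not matched on G+C. NFI (1.86 times, adjusted exact p = 0.256) and POU sites (2.70 times) were also above every shuffled form, so this held for 3 of 12 neural motifs. The HOX-PBX site was found in 2.6% of gaps and 1.5% of summits (adjusted exact p = 0.00109). Its ratio of 1.69 lay inside the range of its shuffled forms (1.501 to 3.113). The comparison thus does not separate that site from base composition and cannot decide whether it lies between peaks. No biological explanation was tested.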
